A study of Mus musculus with 26 samples.

How the data were processed

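Mouse tumours and a mouse cell line were measured. The tumours grew from NT2.5 cells, a mammary tumour line that carries HER2 (neu), after injection into the mammary fat pads of NeuN mice, which carry the same oncogene. Mice received vehicle, entinostat (a small-molecule inhibitor of class I histone deacetylases, mainly HDAC1, HDAC2 and HDAC3), or entinostat with an antibody against the checkpoint receptor CTLA4, against PD1, or against both. Per the labels' protocols, tumours were dissociated enzymatically, red cells were lysed, dead cells were removed with a magnetic kit, no cell type was sorted for sequencing, and 20 droplet libraries were made with the 10x Genomics 3' kit. J774M is a mouse macrophage-type line; its cells were kept in medium with 2.5% fetal bovine serum and received 0.5 micromolar entinostat or DMSO, the solvent, with 3 libraries per treatment. Their bulk RNA libraries were made with a kit that does not mark strand, per the labels' protocols, so reads of a gene and of an overlapping or antisense neighbour cannot be told apart.

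The deposited single-cell matrices hold raw UMI counts per gene and cell, for cells that the authors had already called; the file headers and the submitters' processing notes give Cell Ranger 3.0.2 and the mouse build mm10. Of these, 16 libraries were deposited as 1 aggregated matrix, and whether read depth was equalised between them is not given in the sources used here. The matrix of vehicle replicate p1 has an older layout with no software version in its header. For J774M, the authors deposited a table of estimated counts per gene symbol and a table of TPM, both made with Salmon 0.8.2 per the submitters' processing notes; the genome build and annotation behind them are not given in the sources used here. The percent values below are shares of cells computed here from the deposited barcodes and counts. Groups and sequencing runs were taken from the labels: tumour runs are called A, B, pilot 1 and pilot 2, and a library is named by its group and replicate (A and A1, for example, are from run A).

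Estimated counts of J774M were rounded to whole numbers. Genes were kept with filterByExpr, libraries were scaled with TMM, and entinostat was compared with DMSO by the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are counts scaled by the TMM-adjusted library size.

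Single cells were kept with at least 500 UMIs, at least 200 detected genes and at most 15% mitochondrial UMIs, which left 56717 of 68152 cells. Doublets were called per library with the scrublet method in scanpy 1.11.5 (expected rate 0.06), and the 431 called cells (0.760%) were removed, leaving 56286. Counts were scaled to 10000 per cell and logged, and 2000 variable genes, 30 principal components and 15 neighbours went into Leiden clustering at resolution 1 (leidenalg 0.10.2). The aggregated and the pilot libraries were clustered separately. Clusters were named from 13 marker lists, by the list with the highest mean log2 ratio to the median cluster. Markers of natural killer cells and basal epithelium counted with T cells and epithelium, and the erythroid list was not used to name a cluster. A cluster needed at least 3 detected markers (20 CPM). It stayed unnamed where more of its 10 leading genes belonged to another list than to its own, where over 0.5 of its cells were called doublets, or where its cells' median UMI count was under 0.333 of that of their own libraries with no own marker leading. It also stayed unnamed where a second list scored at least 0.75 of the first. The marker lists were fixed in advance, but this scoring, its limits and the omission of the erythroid list were chosen after the data were seen. With the erythroid list used like the others, 1 pilot cluster of 252 cells, unnamed here, would have been named erythroid, and 0 of the 30 aggregated clusters would have had another name. Names are by likeness to markers only, so each class is an "X-like" group of cells; the short name is used from here on. Of 156 markers, 6 were not among the genes of the matrices (Trac, Trbc1, Trbc2, Ighm, Ighd and Igkc).

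Raw UMI counts were summed per library and class, leaving out a library with fewer than 20 cells of the class, and 1 edgeR quasi-likelihood model per class was fitted to all 20 libraries with group and sequencing run as terms. The 5 classes tested were epithelial cells, macrophages or monocytes, neutrophils, T cells and fibroblasts. The 5 contrasts were entinostat against vehicle, each of the 3 antibody combinations against entinostat alone, and the mean of the 4 entinostat arms against vehicle. Fold changes are within-run estimates, so they can differ from the ratio of group means, because vehicle and entinostat alone include pilot libraries and the antibody arms do not. Shares of cells were compared by the difference in mean percent within runs, with an exact two-sided permutation of treatments within runs and Benjamini-Hochberg adjustment over the classes.

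The 21 gene lists (named with their results) were tested with camera at a preset correlation of 0.01 (limma 3.58.1), adjusted over the lists within each comparison. Camera with an estimated correlation takes the correlation between a list's genes from the data. Its degrees of freedom come from the libraries, while those of the preset version come from the genes. It was run beside the preset version. So was fry, which asks whether a list's genes move in the same direction without comparing them with other genes. Tests, gene lists, marker lists, the rule for the genes named and the alternatives tried were fixed before the data were examined. By that rule, the J774M genes named are the 12 largest rises and 12 largest falls among genes past the threshold with mean log2 CPM of at least 3 and no overlap between the groups. In tumours they are the 5 largest rises and 5 largest falls per class and contrast, with mean log2 CPM of at least 4 and a class mean of at least 0.25 of the gene's highest class mean. That limit lessens free RNA of other classes without excluding it, since in neutrophils a marker of another class reached 0.270. Up to 4 members per list with the smallest p, and Hdac1, Hdac2 and Hdac3, are named whether or not they passed. Predicted genes, mitochondrial and ribosomal protein genes, receptor segments and sex-linked genes are not named, except that where 8 or fewer genes were called, those outside the rule are named and said to be chosen after their values were seen. A gene that the rule names is not reported here, though it stays in its list's counts, medians and tests. Gene positions are from GENCODE for GRCm38, the assembly also called mm10.

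The edgeR gene tests and the comparison of shares were tested on simulated data before use, and the list tests were not. With 200 changed genes drawn into counts like those of J774M (13457 genes in that step), 66.2% of 1.5-fold, 83.3% of 2-fold and 96.9% of 4-fold changes were recovered, 8.57% of the calls were false, and 0 calls were made with no change. For the 4 entinostat arms against vehicle, 2-fold changes were recovered at 87.9% in epithelial cells (12703 genes), 87.9% in macrophages (10259), 85.7% in neutrophils (4910), 32.1% in T cells (2614) and 81.5% in fibroblasts (9312). For entinostat alone against vehicle, 2-fold changes were recovered at 89.4%, 80.3%, 50.8%, 17.9% and 73.8% in the same order. For shares over the 4 arms against vehicle, a shift of 6 points with an SD of 1 was recovered in 20 of 20 draws, and 8 of 160 unshifted tests (5.0%) fell under 0.05. That SD is below those of the larger classes (11.5 for epithelial cells with vehicle). For entinostat alone against vehicle the smallest possible p is 0.125, so no shift could pass.

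Replicates were compared before averaging. Counts of J774M replicates differed by a chi-square of 5.90 to 16.2 per degree of freedom, and those of tumour replicates by 13.8 to 144, so no pair agreed within sampling noise and each library was counted once. The alternatives tried were DESeq2 1.42.0 in place of edgeR, its size factors (RLE), no filter on low counts, limma on log2(TPM + 1), models with or without the replicate number or the run, and only the aggregated libraries. Others were doublets kept, at least 50 cells per class, at least 1000 UMIs per cell, Leiden resolution 0.5, shares of immune cells, and each replicate left out in turn. Added after the data were seen were fits without the pilot 1 pair, with unnamed clusters that scored highest for epithelial markers counted as epithelial, and, for the J774M lists, with the replicate number as a term. Cells in unnamed clusters entered no gene test.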

Results

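The data come from a cell-line experiment and a tumour experiment on entinostat. J774M cells gave 3 bulk RNA libraries with DMSO, with 19164931, 18994215 and 18860512 total estimated counts, and 3 with 0.5 micromolar entinostat, with 18697966, 19142923 and 19705718. Tumours gave 4 single-cell libraries in each of 5 groups: vehicle, entinostat, and entinostat with anti-CTLA4 (the anti-CTLA4 arm), with anti-PD1 (the anti-PD1 arm) or with both (the combined arm). Vehicle and entinostat each had 1 library in run A, run B, pilot 1 and pilot 2, while each antibody arm had 2 libraries in run A and 2 in run B. The tumour libraries held 1503 to 5294 cells and 13800557 (entinostat p2) to 55390456 (combined arm B1) UMIs in all, and the median UMI count per cell ran from 3119 in entinostat p2 to 12484 in vehicle p1, with 7509 in the next library. The labels do not say whether libraries came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

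Entinostat was compared with DMSO in J774M cells to ask what the drug does to gene expression in a macrophage-type cell without a tumour. Mmp9, which encodes the matrix-degrading gelatinase B, rose most among the genes named by the fixed rule, from 1.58 ± 0.317 to 16.6 ± 1.26 CPM (mean ± SD, n = 3). Its log2 fold change was 3.39 (SE 0.17, edgeR adjusted p = 6.7e-11). Gsn, which encodes the actin-severing protein gelsolin, rose from 55.0 ± 4.66 to 178.8 ± 17.3 CPM (log2 fold change 1.70, SE 0.08). Flot1, a scaffold protein of membrane rafts, rose from 14.6 ± 0.397 to 56.1 ± 3.90 CPM (1.94, SE 0.09). Il1rl1, which encodes the IL-33 receptor ST2, fell from 50.7 ± 1.73 to 17.8 ± 1.40 CPM (−1.51, SE 0.09, adjusted p = 7.39e-10). Hs3st1, a heparan sulfate sulfotransferase, had the largest fall among the named genes (−1.62, SE 0.15, adjusted p = 1.21e-07). The other named rises were the focal adhesion protein Tns2 (2.64), Ehd2 (2.24), Akap12 (2.11), the inhibitory receptor Pilra (2.08), Gprc5a (2.07), Tnfrsf23 (1.83), Slc4a8 (1.80), the integrin subunit Itgb7 (1.69) and Trp53inp2 (1.66). The other named falls were Ap4s1 (−1.60), Slfn2 (−1.41), the ADP receptor P2ry12 (−1.38), Gtf3c6 (−1.37), the transcription factor Pax6 (−1.29), the urea transporter Slc14a1 (−1.28), Pced1b (−1.22), the inhibitory collagen receptor Lair1 (−1.18), the interferon-induced Ifi44 (−1.14) and Trmt61a (−1.07). Of the drug's targets, Hdac1 rose from 79.7 ± 3.40 to 108.7 ± 5.09 CPM (0.45, SE 0.07, adjusted p = 6.04e-05), while Hdac2 (0.14, SE 0.07, adjusted p = 0.124) and Hdac3 (0.06, SE 0.07, adjusted p = 0.505) did not pass the test. In all, 4547 of 13721 tested genes passed in edgeR, 2372 higher and 2175 lower, and 552 rose and 128 fell at least 2-fold. The values of the groups did not overlap in 6170 genes (45.0%), where chance gives 10%. The count was 1696 with limma on log2(TPM + 1).

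In GRCm38, Mmp9 (ENSMUSG00000017737) lies on the plus strand of chromosome 2 from 164940780 to 164955850, Gsn (ENSMUSG00000026879) on the plus strand of chromosome 2 from 35256380 to 35307892, and Flot1 (ENSMUSG00000059714) on the plus strand of chromosome 17 from 35823230 to 35832791. Il1rl1 (ENSMUSG00000026069) lies on the plus strand of chromosome 1 from 40429570 to 40465415, Hs3st1 (ENSMUSG00000051022) on the minus strand of chromosome 5 from 39613935 to 39755475, and Hdac1 (ENSMUSG00000028800) on the minus strand of chromosome 4 from 129516104 to 129542713. The values are sums over each gene's transcripts.

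**Figure D1:**
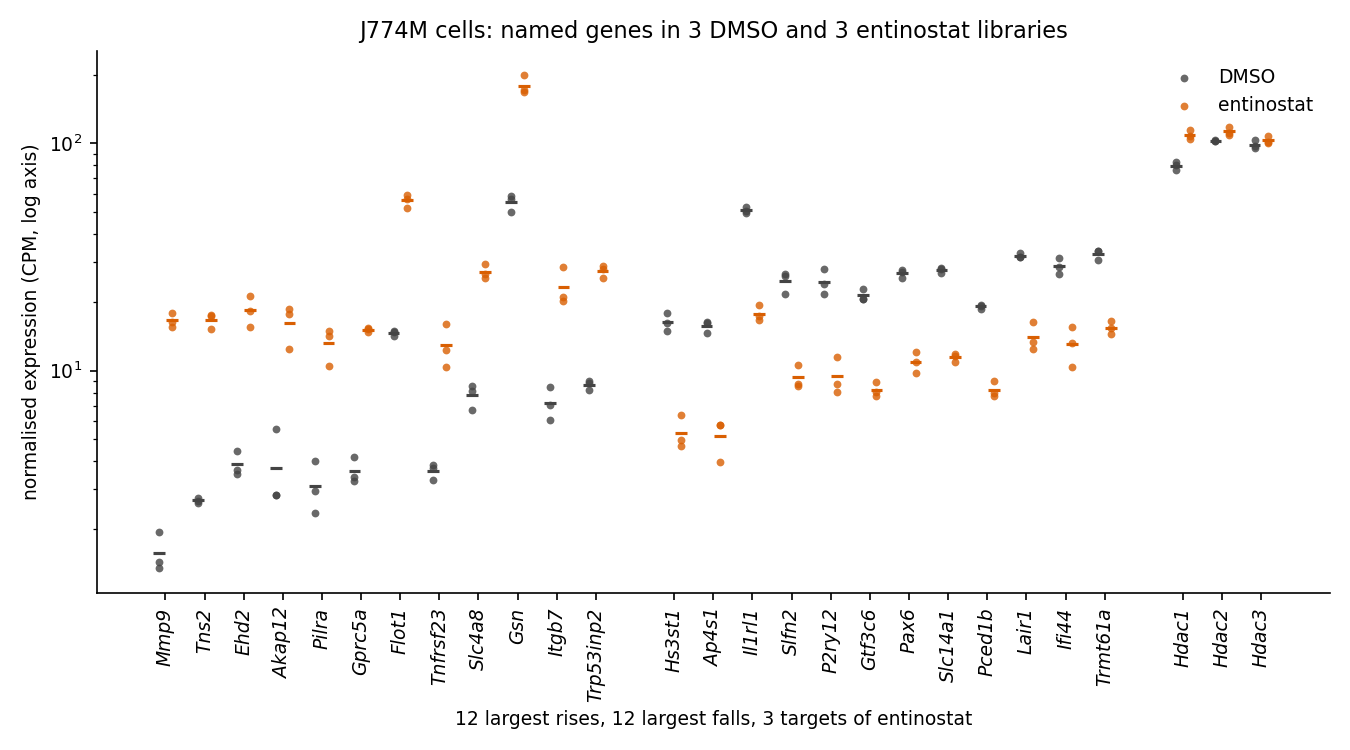
Normalised expression (CPM, log axis) of the named genes in J774M cells, with 1 point per library (3 DMSO in grey, 3 entinostat in orange) and a short bar at each group mean. Mmp9 went from 1.58 to 16.6 CPM and Il1rl1 from 50.7 to 17.8 CPM.

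Of the 21 gene lists, MHC class II presentation moved up in J774M cells. Of its 10 measured genes, 7 rose and 0 fell (8 passed when adjusted over the list alone), with a median log2 fold change of 1.08. Its members included Cd74, the invariant chain (255.7 ± 5.93 to 504 ± 21.1 CPM, n = 3; log2 fold change 0.98), H2-DMa (1.22), H2-Ob (1.70) and H2-Aa (2.23). The list passed camera (adjusted p = 0.000262; adjusted p = 0.184 with an estimated correlation). Proliferation genes moved down, with 0 of 31 higher and 14 lower (16 adjusted over the list alone) and a median of −0.18. Camera gave adjusted p = 0.000275, and adjusted p = 0.411 with an estimated correlation. The mitotic regulators Cdc20 (−0.87), Plk1 (−0.71), Aurka (−0.63) and Ccnb1 (−0.54) were among those that fell. Lysosome and phagocytosis genes had 15 of 28 higher and 3 lower (19 adjusted over the list alone; median 0.23; adjusted p = 0.0038, and adjusted p = 0.184 with an estimated correlation). The protease Ctsd (0.53) and the sialidase Neu1 (0.56) rose, and the Fc receptor Fcgr1 (−0.64) and Gusb (−0.51) fell. MHC class I presentation had 12 of 19 higher and 1 lower (14 adjusted over the list alone; median 0.24; adjusted p = 0.0257, and adjusted p = 0.263 with an estimated correlation). H2-D1 (0.52), H2-K1 (0.54) and the peptide transporter Tap2 (0.51) rose and the immunoproteasome subunit Psmb10 fell (−0.87). H2-D1 and H2-K1 have close paralogs, so their single values are less certain. Suppressive myeloid functions had 7 of 18 higher and 1 lower (8 adjusted over the list alone; median 0.19; adjusted p = 0.0435, and adjusted p = 0.263 with an estimated correlation). The lipid receptor Trem2 fell (−0.86), and Spp1 (0.62), the ectonucleotidase Entpd1 (0.96) and Lgals9 (0.86) rose. Without entinostat replicate 3, 3 lists passed in place of 5, and with an estimated correlation 0 passed. That correlation was −0.0495 for MHC class II, −0.00447 for lysosome and −0.0158 for suppressive myeloid functions. These lie below the preset 0.01, so a higher correlation does not account for their loss. The estimated correlation was 0.0107 for MHC class I and 0.156 for proliferation. For MHC class I, at nearly the preset correlation, camera gave unadjusted p = 0.0488 with the estimate and 0.00489 with the preset. The estimated version has few degrees of freedom with few libraries. That 0 lists passed it therefore does not by itself point to correlated genes. Fry gave adjusted p of 0.000397 (MHC class II) to 0.0108 (proliferation) for the 5 lists, and also passed lists that camera did not.

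The other 16 lists did not pass camera in J774M cells, although single members moved. Interferon-gamma response had 7 of 19 higher and 1 lower (8 adjusted over the list alone; adjusted p = 0.391), with the guanylate-binding genes Gbp4 (1.92) and Gbp7 (1.63) higher. Type I interferon response had 5 of 29 higher and 8 lower (13 alone by that adjustment; adjusted p = 0.61), with Oasl1 lower (−0.74) and Ifit2 higher (0.81). CDK inhibitors and growth arrest had 5 of 14 in each direction (10; adjusted p = 0.784), with Cdkn2c lower (−0.89) and Cdkn1a higher (0.45). Histones outside S phase had 2 of 11 in each direction (4; adjusted p = 0.427), with the linker histone H1f0 at 242.5 CPM rising to 413 (0.77). NF-kB and inflammatory cytokines had 4 of 19 in each direction (9; adjusted p = 0.778), with the chemokine Ccl4 higher (1.17) and Relb lower (−0.70). Extracellular matrix had 4 of 9 higher and 1 lower (6; adjusted p = 0.0832), with Col6a1 higher (2.42) and Fn1 lower (−0.45; the opposite direction, 0.03, with limma on log2(TPM + 1)). Dissociation and heat-shock response had 7 of 15 higher and 3 lower (10; adjusted p = 0.276), with Nr4a1 higher (2.30) and Atf3 lower (−0.67). Regulatory T cell genes had 2 of 7 higher and 1 lower (3; adjusted p = 0.778), with Il1rl1 lower (−1.51), Tnfrsf18 (1.55) and Tnfrsf9 (1.48) higher and a median of −0.59. JAK-STAT signalling had 12 of 38 higher and 9 lower (21; adjusted p = 0.778), and apoptosis 5 of 21 and 3 (11; adjusted p = 0.816). Cholesterol biosynthesis had 8 of 24 higher and 3 lower (11; adjusted p = 0.128), and glycolysis and hypoxia 5 of 25 in each direction (11; adjusted p = 0.778). Histone deacetylases had 2 of 9 higher and 1 lower (3; adjusted p = 0.778), and neuronal genes 2 of 10 and 0 (2; adjusted p = 0.117). Cytotoxic lymphocyte functions had 2 of 10 higher and 1 lower (3; adjusted p = 0.589), and inhibitory receptors and exhaustion 1 of 4 and 0 (1; adjusted p = 0.778). The median was below 0 and the test pointed up for histone deacetylases, apoptosis, interferon-gamma response, JAK-STAT signalling and inhibitory receptors. For glycolysis the median (−0.03) and the test pointed down and the mean (0.03) up.

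**Figure D2:**
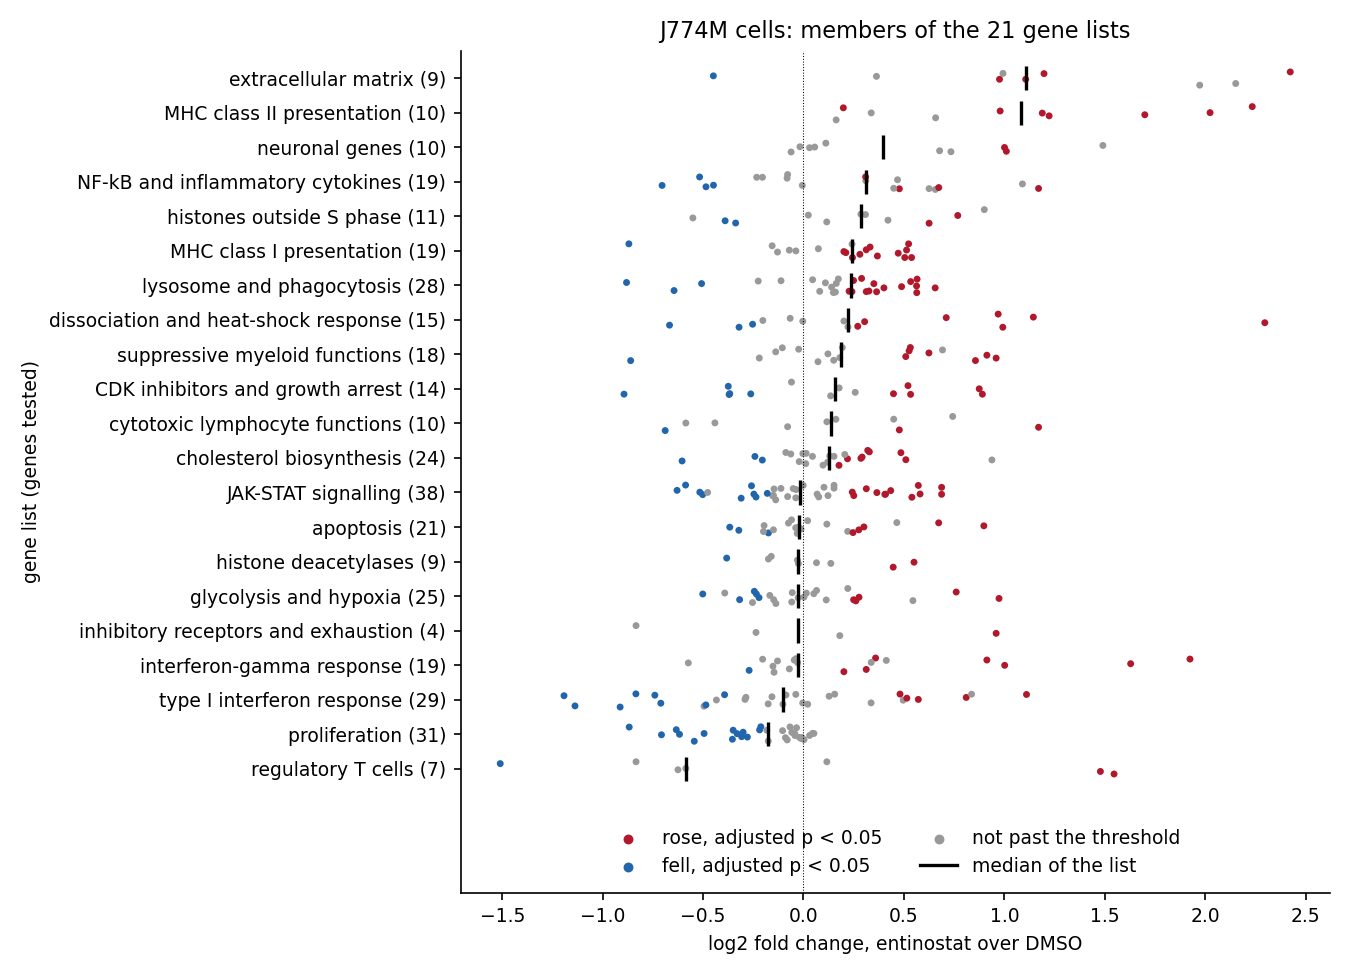
Log2 fold change of each tested member of the 21 lists in J774M cells, entinostat over DMSO, with 1 point per gene (red rose, blue fell, grey did not pass) and a bar at the list's median. MHC class II presentation has a median of 1.08 and proliferation one of −0.18.

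In the tumours, the question was which cells were present under each treatment and how their expression differed. Of 56286 kept cells, 20344 were epithelial, 12563 macrophages or monocytes, 10169 neutrophils, 3115 fibroblasts, 2262 endothelial, 1344 T cells, 994 mural and 351 dendritic, and 5144 were in unnamed clusters. The largest unnamed cluster, of 4087 cells before doublets were removed, scored highest for epithelial markers (2.03, next list 0.094). It stayed unnamed because haemoglobin genes led it, so the epithelial shares may be too low. T cells made up 1.02% ± 0.723 of kept cells with vehicle (SD, n = 4), and 2.97% ± 1.75 with entinostat. They made up 3.81% ± 1.57 in the anti-CTLA4 arm, 2.69% ± 1.34 in the anti-PD1 arm and 1.96% ± 0.913 in the combined arm. Epithelial cells made up 43.0% ± 11.5 with vehicle, 34.0% ± 8.17 with entinostat, and 31.7% ± 7.60, 32.7% ± 6.81 and 40.4% ± 5.25 in the antibody arms in the same order. For entinostat against vehicle, the T cell share differed by 1.95 points and lay higher in 4 of 4 runs, by 1.90 in A, 1.10 in B, 0.69 in pilot 1 and 4.10 in pilot 2 (exact p = 0.125, the smallest this design allows; adjusted p = 0.562). Vehicle p1 held 1 T cell among 1488 kept cells, so the vehicle value of pilot 1 rests on 1 cell. In the pilot libraries the median UMI count was 1390 in the T cell cluster, and 1055.5 and 788 in the neutrophil clusters. Over the cells of vehicle p1 it was 12484, and 1490 of these 1503 cells passed the filter, against 2521 of 2938 in entinostat p1. The pilot 1 differences may therefore reflect which cells were called, which was not tested. Without entinostat p2 or vehicle p2 the T cell difference was 1.23 points. The epithelial share differed by −8.96 points, by −7.10 in A, −0.903 in B, −18.9 in pilot 1 and −8.98 in pilot 2 (exact p = 0.125, adjusted p = 0.562). Over the 4 entinostat arms against vehicle the T cell difference was 1.85 points (exact p = 0.0664, adjusted p = 0.334), and 1.10 points without entinostat p2 or vehicle p2. The epithelial difference was −8.87 points (exact p = 0.0742, adjusted p = 0.334). Both held in 4 of 4 runs, pilot 1 included. Without vehicle p1, which held 0 neutrophils, or without entinostat p1, the epithelial differences were −5.66 points with entinostat and −5.54 over the 4 arms. No class passed the threshold after adjustment in any of these comparisons.

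The macrophage share was 21.6% ± 2.48 with vehicle and 24.3% ± 5.80 with entinostat, and 23.7%, 24.4% and 18.6% (SD 3.76, 3.65 and 3.19) in the anti-CTLA4, anti-PD1 and combined arms. In the order of these 5 groups the fibroblast share was 6.04%, 5.92%, 5.32%, 5.49% and 5.39%, and the endothelial share 4.05%, 4.43%, 3.79%, 4.15% and 3.82%. Neutrophils made up 14.6% ± 9.87 with vehicle, 18.7% ± 1.94 with entinostat, and 18.4%, 18.7% and 17.4% in the antibody arms, but vehicle p1 held 0 neutrophils among 1488 kept cells, which allows a share of up to 0.202% (counting error only). Without vehicle p1, or without entinostat p1, the neutrophil difference between entinostat and vehicle went from 4.15 to −0.873 points, and that of the 4 arms from 3.49 to −1.75. Unnamed clusters held 7.73% of cells with vehicle, 7.17% with entinostat, and 10.4%, 9.32% and 10.2% in the antibody arms. In runs A and B, the largest of them, which scored as epithelial, held 7.36% of all entinostat cells. It held 9.42%, 8.56% and 9.10% of the cells of the antibody arms in the same order. Against entinostat alone, the antibody arms together differed by −0.614 points in mural cells and by 2.42 points in unnamed clusters (exact p = 0.0408 and adjusted p = 0.184 for both). Only entinostat A and B enter this comparison. The mural difference was −0.311 points without entinostat B, and that of unnamed clusters was 4.12 in run A and 0.718 in run B. T cells differed by −0.221 points (exact p = 0.898). Haemoglobin RNA, a trace of red cells, differed between libraries. It was 297.2, 1212, 496 and 334.6 CPM in vehicle A, B, p1 and p2, and 7.16, 905.6, 428 and 589.9 CPM in the matching entinostat libraries. In the antibody arms it ran from 1.41 CPM (anti-CTLA4 arm B1) to 110.3 CPM (anti-PD1 arm B1).

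**Figure D3:**
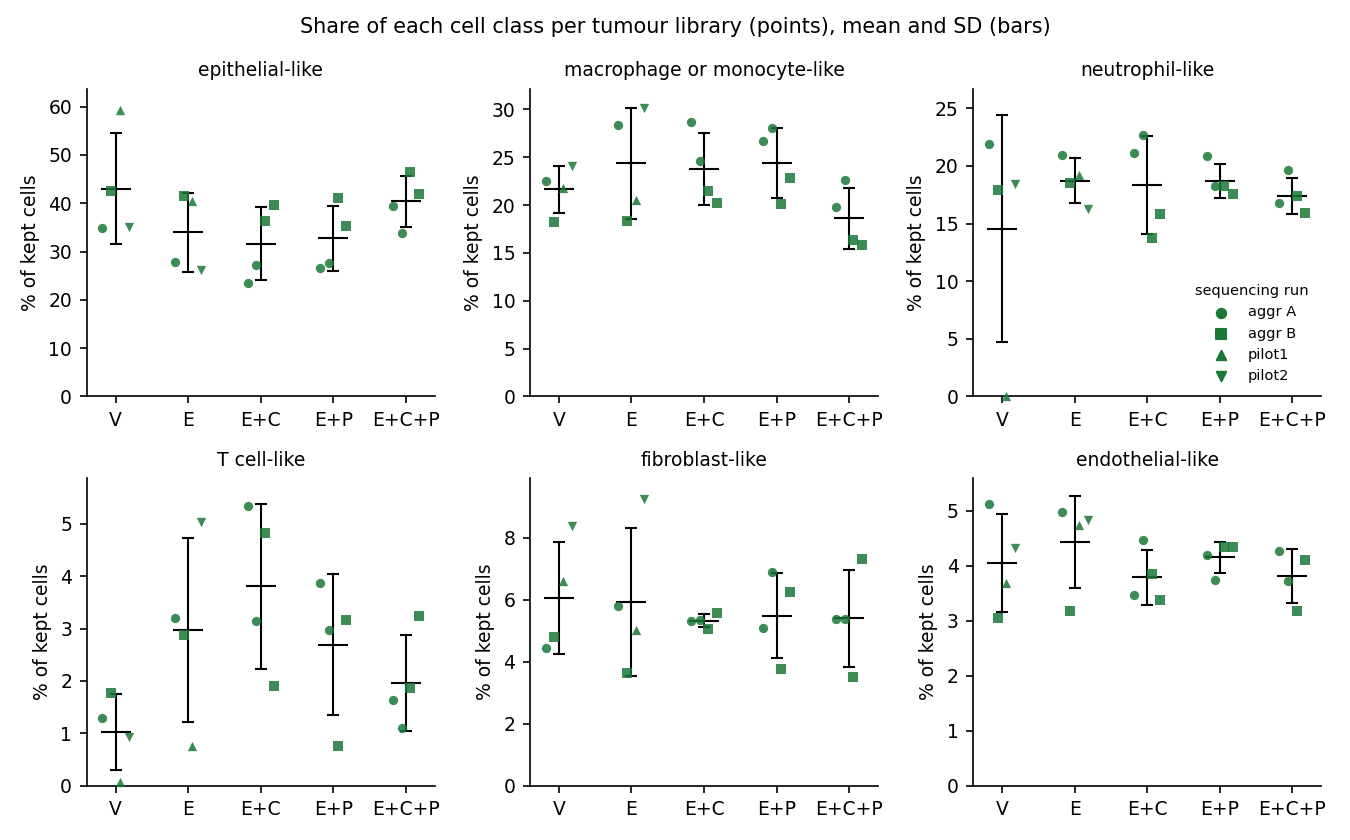
Share of kept cells (%) in 6 classes per tumour library (points, with the marker giving the sequencing run), with group mean and SD (bars), for vehicle (V), entinostat (E) and entinostat with anti-CTLA4 (E+C), anti-PD1 (E+P) or both (E+C+P). The T cell mean is 1.02% with vehicle and 2.97% with entinostat, and the neutrophil point at 0 is vehicle p1.

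In neutrophils with entinostat, Fas, the death receptor, rose from 34.8 ± 12.1 CPM (n = 3) to 92.1 ± 55.5 CPM (n = 4; log2 fold change 1.66, SE 0.36, edgeR adjusted p = 0.0195). Ifit1bl2, of an interferon-induced family with close paralogs, rose from a mean of 7.11 to 21.3 CPM (1.95, SE 0.49, adjusted p = 0.0276). Sh2d3c (1.59), the biliverdin reductase Blvrb (1.38) and the vitamin C transporter Slc23a2 (1.38) also rose. Ltc4s, the leukotriene C4 synthase, fell from 417.5 ± 44.6 to 273.8 ± 96.8 CPM (−0.86, SE 0.19, adjusted p = 0.0131), as did Pspc1 (−1.77), Nek7 (−1.35), the proteasome subunit Psmd6 (−1.23) and Fam105a (−0.84). Each of these 10 genes had the same sign in 3 of 3 runs. They were chosen by their change in these same runs, so this is no separate support. Fas, Ifit1bl2 and Ltc4s had their highest class mean in neutrophils, while the other 7 had it in another class (Nek7, for example, at 27.1 CPM in neutrophils and 84.4 in T cells). In GRCm38, Fas (ENSMUSG00000024778) spans 34290666 to 34327772 on chromosome 19 (plus strand) and Ltc4s (ENSMUSG00000020377) 50236461 to 50238616 on chromosome 11 (minus strand). Of 5151 tested genes, 153 passed, 129 higher and 24 lower. Of the lists, CDK inhibitors and growth arrest passed camera with 2 of 11 genes higher (6 adjusted over the list alone; median 0.38; adjusted p = 0.00356, and adjusted p = 0.256 with an estimated correlation). The genes that rose were Cdkn1a, which encodes the inhibitor p21 (0.58, adjusted p = 0.037), and Cdkn1b (0.70). NF-kB and inflammatory cytokines passed with 3 of 21 higher (5 adjusted over the list alone; median 0.37; adjusted p = 0.00356, and adjusted p = 0.555 with an estimated correlation). These were Nfkbiz (0.65), the inhibitor Nfkbia (0.45) and Relb (0.77). Dissociation and heat-shock response passed with 4 of 17 higher (7 adjusted over the list alone; median 0.35; adjusted p = 0.0362, and adjusted p = 0.518 with an estimated correlation). These were the immediate-early genes Egr1 (0.78), Zfp36 (0.62), Ier3 (0.75) and Junb (0.40). A cluster led by S100a8 held 51.6% of neutrophils in entinostat A, 32.5% in B, 32.6% in p1 and 59.5% in p2, against 32.4%, 26.3% and 36.9% in vehicle A, B and p2. The count of 153 fell to 6 without entinostat A, 15 without vehicle A, 10 without vehicle p2, 23 without entinostat p2 and 97 without anti-PD1 arm B2. It was 10 in the aggregated libraries alone and 0 without the run as a term (edgeR).

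Over the 4 entinostat arms against vehicle, 304 genes passed in neutrophils, 240 higher and 64 lower. The named rises were Ifit1bl2 (1.53), the glutathione-synthesis subunit Gclm (1.39), Sh2d3c (1.38), the microRNA-155 host gene Mir155hg (1.37) and Inafm2 (1.34). The named falls were Ccdc86 (24.3 to 13.6 CPM), the caspase Casp6 (−0.89), Timm50 (−0.83), Stk38l (−0.82) and Pmf1 (−0.79). Of these 10, Ifit1bl2 and Gclm had their highest class mean in neutrophils and 8 in another class. The same 3 lists passed camera. NF-kB had 5 of 21 higher (6 adjusted over the list alone; median 0.44; adjusted p = 0.000433, and adjusted p = 0.422 with an estimated correlation). Nfkbiz (0.65), Relb (0.82), Tnfaip3 (0.63) and Nfkbia (0.44) were among them. CDK inhibitors had 3 of 11 higher (7 adjusted over the list alone; median 0.34; adjusted p = 0.00615, and adjusted p = 0.365 with an estimated correlation), namely Gadd45a (0.67), Mdm2 (0.55) and Cdkn2d (0.46). Dissociation and heat-shock response had 5 of 17 higher (5 adjusted over the list alone; median 0.28; adjusted p = 0.0278, and adjusted p = 0.422 with an estimated correlation). The count was 18 without vehicle A, 108 without vehicle p2, 127 without entinostat p2 and 172 without vehicle B, 111 in the aggregated libraries alone and 3 without the run as a term.

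**Figure D4:**
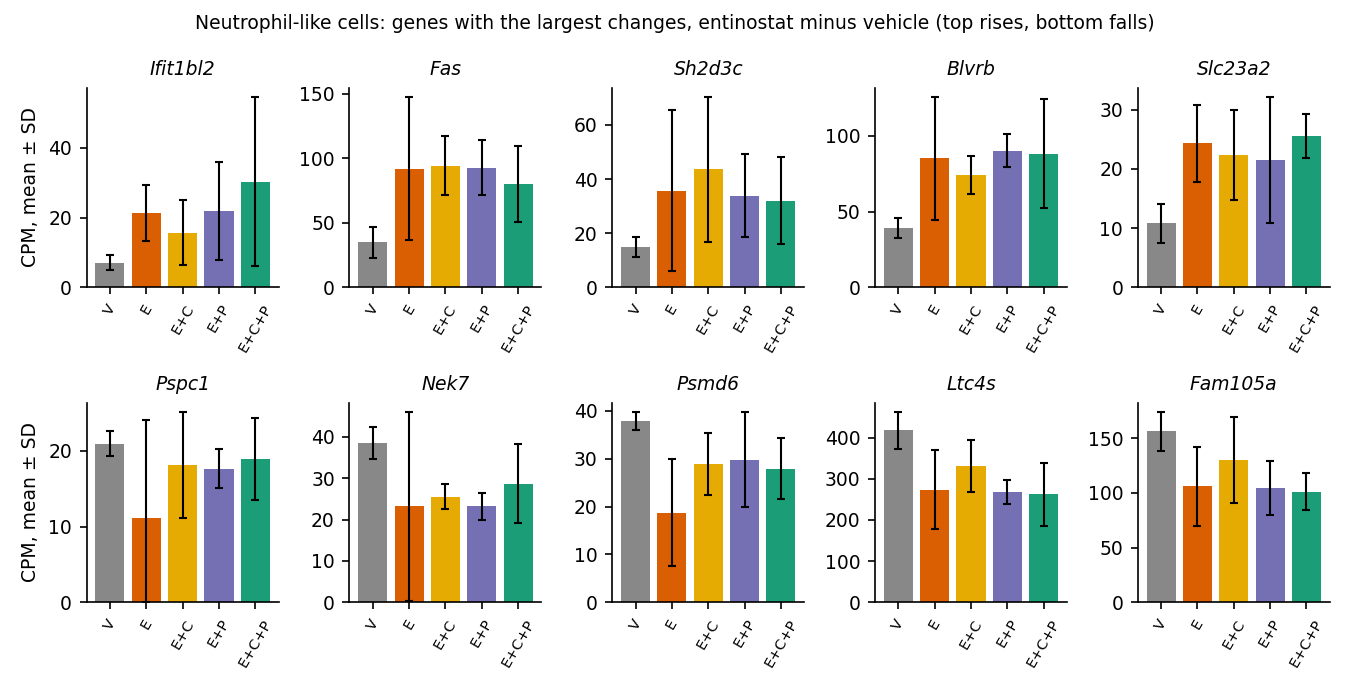
Mean CPM of the 5 largest rises (top) and 5 largest falls (bottom) in neutrophils with entinostat, for vehicle (V, n = 3), entinostat (E) and entinostat with anti-CTLA4 (E+C), anti-PD1 (E+P) or both (E+C+P); error bars are SD and lower ends stop at 0. Fas is at 34.8 CPM with vehicle and 92.1 CPM with entinostat, and Ltc4s at 417.5 and 273.8 CPM.

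In macrophages, MHC class II presentation passed camera as it did in J774M cells. With entinostat, the median of its 12 genes was 0.49. Of these, 0 passed over all genes and 8 were higher when adjusted over the list alone (adjusted p = 1.43e-08, and adjusted p = 0.474 with an estimated correlation). H2-DMa had 484 CPM with vehicle and 661 with entinostat (0.46), H2-DMb1 458 and 613.7 (0.42), H2-Ob 7.46 and 15.6 (1.07) and H2-Oa 3.03 and 8.80 (1.58). Proliferation genes had a median of −0.38 (31 genes, 0 past over all genes; adjusted p = 1.27e-05, and adjusted p = 0.561 with an estimated correlation). Extracellular matrix had a median of −0.40 and MHC class I presentation 0.18 (both adjusted p = 0.0015), and cholesterol biosynthesis 0.20 (adjusted p = 0.002), with adjusted p = 0.561 with an estimated correlation for each. The matrix gene Postn had 0.00329 of its fibroblast mean in macrophages. Of 10408 genes, 0 passed in edgeR (1037 at unadjusted p under 0.05; 56 in DESeq2). The count was 66 without entinostat p1, 74 without vehicle p1, 10 without combined arm A2, 12 without combined arm B2, 3 without anti-CTLA4 arm B2, 2 without entinostat p2 or vehicle p2 and 1 without anti-CTLA4 arm B1. It was 6 at Leiden resolution 0.5, 65 without the pilot 1 pair and 457 with no filter on low counts.

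Over the 4 arms against vehicle, 8 genes rose in macrophages. They included the transcription factors Prdm1 (25.7 ± 6.20 to 35.5 ± 7.26 CPM; 0.66, SE 0.12, adjusted p = 0.0221) and Runx3 (121.8 to 165.2 CPM; 0.51, SE 0.09, adjusted p = 0.0207). Others were Ngfrap1 (0.49), Msl2 (0.48) and the MYC antagonist Mxi1 (0.39). The last 3, outside the naming rule and named after their values were seen, were Selm (0.59), Mefv (0.87) and the costimulatory ligand Cd80 (0.83). Of the 8, Mxi1 had its highest class mean in macrophages, and the other 7 had it in another class. Their macrophage means ranged from 0.0743 (Selm) to 0.767 (Runx3) of that highest mean. MHC class II presentation had a median of 0.36 (8 of 12 higher adjusted over the list alone and 0 over all genes, adjusted p = 9.14e-07, and adjusted p = 0.737 with an estimated correlation). Proliferation (−0.31, adjusted p = 0.000443), MHC class I presentation (0.17, adjusted p = 0.0233) and type I interferon response (−0.15, adjusted p = 0.0299) also passed camera, each with adjusted p = 0.817 with an estimated correlation. The count of 8 became 0 without vehicle A or vehicle B, 1 without entinostat p2 or vehicle p2, 111 without vehicle p1 and 112 without entinostat p1. It was 54 without anti-CTLA4 arm B2, 35 without combined arm A2, 30 without anti-PD1 arm B1, 19 without combined arm B2 and 13 without anti-PD1 arm A1. By setting it was 0 without the run as a term, 2 in the aggregated libraries alone, 13 at Leiden resolution 0.5, 22 with RLE size factors, 81 in DESeq2, 116 without the pilot 1 pair and 613 with no filter on low counts.

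In epithelial cells, which hold the tumour cells, cholesterol biosynthesis was the list with the smallest p. With entinostat its 24 genes had a median of 0.24 (12 higher adjusted over the list alone, 0 over all genes; adjusted p = 7.64e-16, and adjusted p = 0.138 with an estimated correlation). Hmgcs1, which makes HMG-CoA, was at 15.7 ± 0.983 CPM with vehicle and 19.6 ± 2.80 with entinostat (n = 4 each; 0.31), and Fdps at 89.2 and 104.2 (0.21), each higher in 4 of 4 runs. Both were chosen by their p in these same runs, so the equal signs are no separate support. Over the 4 arms the median was 0.26 (19 higher adjusted over the list alone; adjusted p = 2.5e-19, and adjusted p = 0.0983 with an estimated correlation). With entinostat alone NF-kB (−0.49, adjusted p = 0.00508), extracellular matrix (−0.12, adjusted p = 0.00561), suppressive myeloid functions (−0.22, adjusted p = 0.0175), lysosome (−0.07, adjusted p = 0.0175), JAK-STAT signalling (−0.08, adjusted p = 0.0232) and MHC class I presentation (0.10, adjusted p = 0.0235) also passed. In that order they had adjusted p of 0.388, 0.495, 0.41, 0.388, 0.138 and 0.556 with an estimated correlation. Of single members, Cxcl2 (NF-kB) was at 0.00174 and Ncf1 (suppressive myeloid) at 0.00338 of their neutrophil mean in epithelial cells, and Lox (extracellular matrix) at 0.00171 of its fibroblast mean. Lysosome genes also passed over the 4 arms (−0.08, adjusted p = 0.00138, and adjusted p = 0.267 with an estimated correlation). Of 12838 genes 3 fell with entinostat, named here after their values were seen: Styx (−2.77, SE 0.34, adjusted p = 0.000993), Lamtor3 (−1.02, SE 0.16, adjusted p = 0.0409) and the predicted gene Gm10269 (−1.04). Styx and Lamtor3 had their highest class means in endothelial and dendritic cells. The count of 3 became 0 without entinostat p1 or vehicle p1, 6 without combined arm A2 and 7 without entinostat B. It was 1 without any of anti-CTLA4 arm A1, A2, B1 and B2, anti-PD1 arm A1, A2 and B1, vehicle B, entinostat p2 and vehicle p2. By setting it was 0 without the run as a term or in the aggregated libraries alone, 1 at Leiden resolution 0.5, 9 with no filter on low counts and 22 in DESeq2. Over the 4 arms 0 passed in edgeR (1380 at unadjusted p under 0.05; 86 in DESeq2). The count was 6 without combined arm A2, 3 without entinostat p2, and 2 without entinostat A or vehicle p2. It was 1 with unnamed clusters counted as epithelial, 19 without the run as a term and 24 with no filter on low counts.

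**Figure D5:**
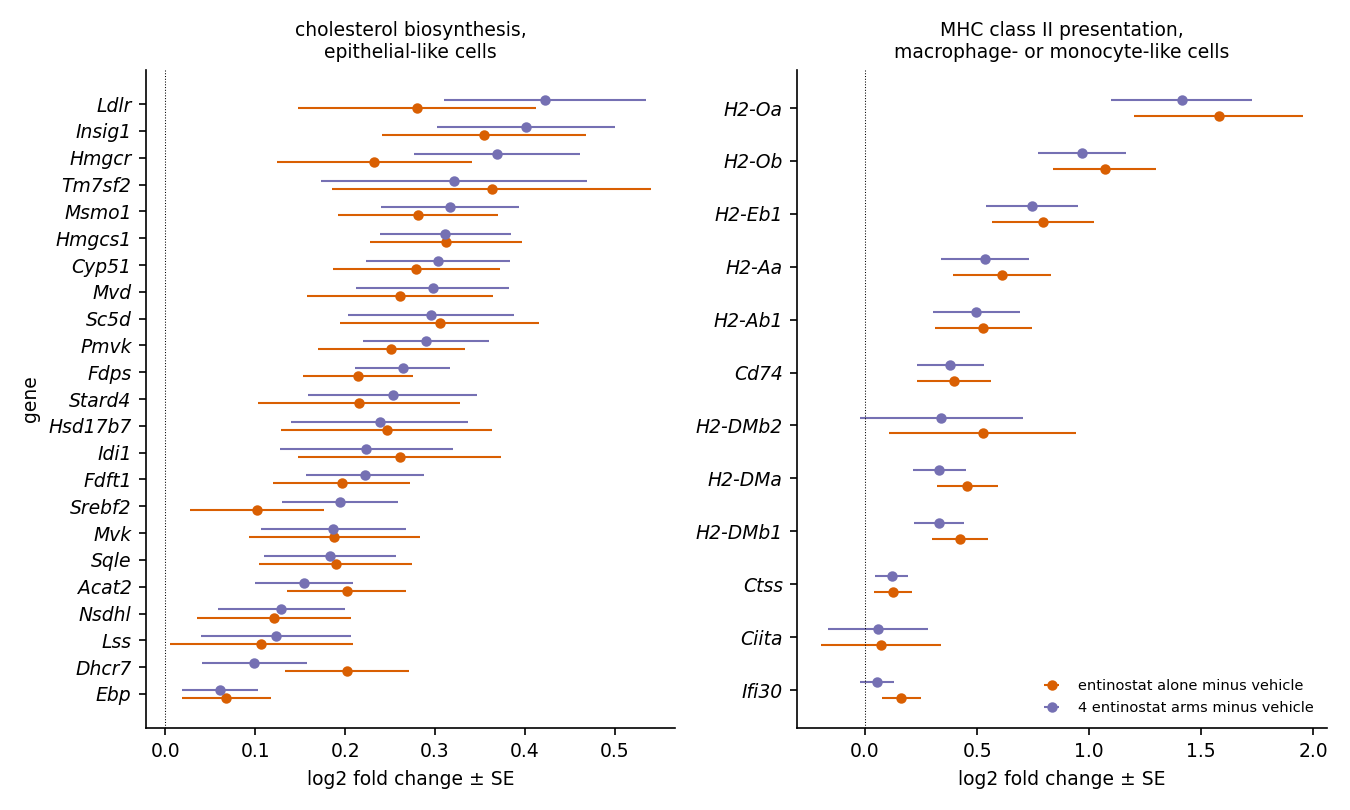
Log2 fold change and SE of 23 of the 24 members of cholesterol biosynthesis in epithelial cells and of the members of MHC class II presentation in macrophages, for entinostat (orange) and the 4 entinostat arms (purple) against vehicle. The list medians with entinostat are 0.24 and 0.49.

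In T cells, regulatory T cell genes passed camera with entinostat. The median of 10 genes was 0.98 (4 higher adjusted over the list alone, 0 over all genes; adjusted p = 8.43e-07, and adjusted p = 0.706 with an estimated correlation). Il2ra, the high-affinity IL-2 receptor chain, had means of 163.7 CPM with vehicle and 428 CPM with entinostat (n = 3 each; 1.37, SE 0.42), and the checkpoint receptor Ctla4 at 227.4 ± 93.7 and 577.8 ± 226 (1.40). Il10 had 0 counts in every vehicle library and a mean of 83.3 CPM with entinostat. That mean was 8.07 times a floor of 3 counts over the vehicle group, and the mean over the 4 arms was 3.33 times it. These ratios take no account of the spread between entinostat libraries. With entinostat, the list's median with Il10 at this ratio was also 0.98. Over the 4 arms the list had a median of 0.59 (2 higher adjusted over the list alone; adjusted p = 0.000889, and adjusted p = 0.979 with an estimated correlation). Inhibitory receptors and exhaustion had a median of 0.77 over 4 genes (2 higher adjusted over the list alone; adjusted p = 0.0128, and adjusted p = 0.673 with an estimated correlation), with Lag3 at 2.89 and Ctla4 at 1.32. Of 2775 genes 2 fell with entinostat and 1 over the 4 arms, named after their values were seen: the predicted genes Gm8730 (−0.79) and Gm10260 (−1.95 with entinostat, −1.35 over the arms), both with higher means in epithelial cells. The 2 became 0 without entinostat A or B, vehicle A or anti-CTLA4 arm A2, B1 or B2, and 1 without combined arm A1, A2 or B2, vehicle B or p2, or entinostat p2. The count of 1 became 0 without anti-CTLA4 arm A1, A2 or B1, anti-PD1 arm A2, vehicle A or combined arm B1 or B2, 8 without anti-PD1 arm B1 and 3 without entinostat p2 or vehicle p2. It was 2 without entinostat A or B, anti-PD1 arm A1 or B2, combined arm A1 or A2, or anti-CTLA4 arm B2. Both counts were 0 without the run as a term, 1 and 0 in the aggregated libraries alone and in DESeq2, and 16 and 20 with no filter on low counts. The count over the 4 arms was also 0 with RLE size factors or Leiden resolution 0.5, and 2 with doublets kept. The class held 139 vehicle cells, and 17.9% of simulated 2-fold changes were recovered.

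In fibroblasts, cholesterol biosynthesis (22 genes, median 0.26, adjusted p = 0.00309) and extracellular matrix (25 genes, median 0.14, adjusted p = 0.00924) passed camera with entinostat, each with adjusted p = 0.497 with an estimated correlation. Hmgcs1 had 27.8 CPM with vehicle and 41.4 with entinostat (0.57), and the collagen gene Col6a2 1038 and 1207 (0.23). In these lists 1 and 0 members passed adjusted over the list alone. Of 9491 genes 0 passed in edgeR with entinostat (235 at unadjusted p under 0.05; 3 in DESeq2; 2 without entinostat p2 or vehicle p2 and 1 without combined arm B2). Over the 4 arms 0 passed in edgeR (454 at unadjusted p under 0.05; 0 in DESeq2; 1 without entinostat p2 or vehicle p2). With no filter on low counts these were 102 and 142. Proliferation (−0.14) and extracellular matrix (0.10) passed camera over the 4 arms with adjusted p = 0.0371 and type I interferon response (0.16) with adjusted p = 0.0442, each with adjusted p = 0.92 with an estimated correlation. Hdac1, Hdac2 and Hdac3 did not pass in any tumour class with entinostat, where Hdac3 was not tested in T cells; Hdac1 was at −0.32 in epithelial cells and −0.31 in macrophages.

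The antibody arms were compared with entinostat alone to ask what checkpoint antibodies add. The entinostat libraries also enter the comparison of entinostat with vehicle. Their own deviations therefore push both comparisons in opposite directions. A list with opposite signs in them does not by itself show an antibody effect. In T cells, regulatory T cell genes were lower in the anti-PD1 arm (median −0.75; 3 lower adjusted over the list alone; adjusted p = 2.54e-05, and adjusted p = 0.705 with an estimated correlation), with Tnfrsf18 at −0.87 and Il2ra at −1.03. They were also lower in the combined arm (−0.63; adjusted p = 0.00369, and adjusted p = 0.85 with an estimated correlation). In epithelial cells of the anti-CTLA4 arm, proliferation genes were lower (median −0.16; 11 lower adjusted over the list alone; adjusted p = 7.6e-08, and adjusted p = 0.93 with an estimated correlation), with Rrm2 at −0.40 and Mcm4 at −0.38. Without the run as a term this list pointed the other way (adjusted p = 0.582). Here and below, that fit lets differences between runs into the comparison, since the antibody arms have no pilot libraries. In the pilot libraries, a cluster of 304 cells that scored highest for epithelial markers stayed unnamed. Its leading genes included Top2a and Rrm2, so the epithelial sums of the pilot libraries lack these cells. In macrophages, extracellular matrix was higher in the anti-PD1 arm (0.41, adjusted p = 0.000807, and adjusted p = 0.806 with an estimated correlation) and in the combined arm (0.64, adjusted p = 1.86e-05, and adjusted p = 0.741 with an estimated correlation). In the combined arm MHC class II presentation was lower (−0.23, adjusted p = 0.0186, and adjusted p = 0.741 with an estimated correlation), and it pointed the other way without the run as a term (adjusted p = 0.648). The matrix gene Col4a2 had 0.00636 of its endothelial mean in macrophages. In fibroblasts, type I interferon response was higher in the anti-CTLA4 arm (0.42, adjusted p = 0.000532, and adjusted p = 0.567 with an estimated correlation) and the anti-PD1 arm (0.43, adjusted p = 0.00572, and adjusted p = 0.935 with an estimated correlation). Of 105 class and list pairs, 6 passed in the anti-CTLA4 arm, 8 in the anti-PD1 arm and 12 in the combined arm, and 0 in each with an estimated correlation. No single gene passed in edgeR in any of the 5 classes. Recovery of changed genes was not simulated for these comparisons. Of the entinostat libraries, only A and B share a run with the antibody arms. The lack of passing genes therefore does not show that the antibodies add nothing. The counts at unadjusted p under 0.05 for the anti-CTLA4, anti-PD1 and combined arms were 1043, 713 and 671 in epithelial cells (5, 0 and 2 in DESeq2) and 480, 403 and 626 in macrophages (1, 0 and 0). They were 224, 193 and 349 in neutrophils (0, 1 and 0), 90, 136 and 102 in T cells (0, 0 and 1) and 497, 369 and 400 in fibroblasts (1, 0 and 0). With no filter on low counts 3, 1 and 4 genes passed in epithelial cells, 68, 107 and 211 in macrophages, 2, 0 and 24 in neutrophils, 3, 1 and 0 in T cells and 79, 71 and 164 in fibroblasts. Leaving out 1 library gave at most 1 gene in epithelial cells, macrophages and fibroblasts. This was in the combined arm in epithelial cells without combined arm A1, entinostat B, entinostat p2 or vehicle p2, and in fibroblasts without vehicle A, entinostat p2 or vehicle p2. In macrophages it was in the anti-PD1 arm without combined arm B2 and in the combined arm without combined arm A1. It gave 2 in T cells (anti-PD1 arm without anti-PD1 arm B2), and in neutrophils 1 in the anti-CTLA4 arm and 3 in the combined arm without entinostat B, and 1 in the combined arm without anti-PD1 arm B1 or combined arm B2.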

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

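No test in this part was chosen after its result was seen, apart from the fits without the pilot 1 pair and the comparison of neutrophil genes with markers of other classes. The splits within runs were added after those across runs had been seen. Of 53 sets of 4 libraries, 3 held a library far from the others, and chance gives about 1 in 20 such sets. The median share of mitochondrial UMIs was 2.80% in anti-CTLA4 arm A1, against 3.44% to 3.53% in the other libraries of that arm. Dendritic cells made up 0.359% of kept cells in combined arm A1, against 0.502% to 0.511% in the other combined arm libraries. Endothelial cells made up 3.19% in entinostat B, against 4.74% to 4.98% in the other entinostat libraries. These came from 4 runs, which the comparison does not take into account, and vehicle B, at 3.06%, was also the lowest of its group (vehicle A 5.14%).

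The genes that passed in neutrophils with entinostat were weighed against free RNA, a shift between neutrophil clusters and chance. Of the 153 genes, 62.1% had their highest class mean in neutrophils, against 21.3% of all 5151 tested genes, which argues against free RNA from other cells for these 95. For the other 58, among them 7 of the 10 named, it stays open, since 69.0% of them, fewer than the limit set for excluding it, exceeded every marker of epithelial, fibroblast, endothelial, mural and T cells in their neutrophil share of the highest class mean (highest marker 0.270). A shift between clusters stays open: the median change was 0.790 in the whole class and was kept to a ratio of 0.738 inside the S100a8-led cluster and 0.604 inside the others, so a part of it may come from the shift. Of 34 splits that could be fitted, 2 gave as many genes, the real one included, but the highest other (153) is its mirror image and was bound to do so, so this tally does not bear on chance; the next split gave 142, and chance stays open.

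MHC class II genes in macrophages were weighed against vehicle p1, whose matrix has an older layout, and against a shift between macrophage clusters. Vehicle p1 is argued against as the cause, because the median without the pilot 1 pair was 1.30 times that of all libraries (0.64 against 0.49 on the log2 scale). A shift between clusters cannot be excluded, since the median inside the largest macrophage cluster was 0.597 of the whole-class value. An effect of the treatment is untested beyond this and is a hypothesis.

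Pseudogenes stood out in pilot 1. In macrophages the median log2 ratio of vehicle to entinostat over 21 pseudogenes, less that over 8164 protein-coding genes, was 2.45 in pilot 1, 0.44 in run A, 0.19 in run B and −0.13 in pilot 2. The older layout of vehicle p1 is a candidate explanation; the value in run A is beyond what it would give, so it stays open. In epithelial cells with entinostat, 3 of 34 splits gave as many as the 3 genes found and the highest other gave 13, so chance is not excluded. No gene passed there without vehicle p1 or without entinostat p1, so the 3 genes depend on the pilot 1 pair. Styx was at 1.90 ± 2.24 CPM with vehicle (mean ± SD, n = 4). Whether vehicle p1 is the cause was not tested.

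Splits of the libraries were drawn across runs, with the run as a term, and for the 4 arms also within runs, which keeps treatment and run apart. In neutrophils over the 4 arms, 1 of 60 splits, the real one, gave 304 genes in each way. The highest other gave 62 across runs and 32 within runs, so chance is argued against, although the count was 18 without vehicle A and 3 without the run as a term. The fit without that term lets differences between runs into the comparison, so its count cannot be read as a test of chance. In macrophages over the 4 arms, 2 of 60 splits gave as many as the 8 genes across runs (highest other 21) and 1 of 60 within runs (highest other 7). Both shares are under 0.05, but the highest other splits lie near or above 8 and the count was 0 without vehicle A or vehicle B, so the evidence against chance is weak. In T cells over the 4 arms, 9 of 60 gave as many as the 1 gene across runs (highest other 2) and 9 of 60 within runs (highest other 85), so chance is not excluded. The split with 85 genes stands alone, since the next highest within runs gave 3, and what sets it apart was not tested. For entinostat alone against vehicle, exchanges within runs are too few for a share under 0.05. The 10 splits of T cells with entinostat (2 genes, highest other 1) and of J774M (4547 genes, highest other 0) are also too few. The real split alone reached its count, 1 of 10 in each.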

How the results depend on the processing

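The J774M gene count of 4547 stayed within 1.5 times under 10 of 11 alternatives, and was 1696 with limma on log2(TPM + 1), where Fn1 went to 0.026. The cause was not tested. Of alternative values for single J774M genes, 1106 kept direction and side of the threshold, 35 lost it, 4 gained it and 1 reversed. With the replicate number as a block, 4220 J774M genes and 6 lists passed. Same-numbered J774M libraries had correlations of 0.027, 0.0061 and −0.092 in their deviations. With 3 libraries per treatment these values show no sign of pairing and cannot exclude it. Leaving out 1 library gave 3 to 7 J774M lists. In the tumours 561 alternative gene counts were within 1.5 times and 152 were not, and 459 shares kept their direction and 38 did not. Most of the main gene counts were 0, and 0 in both fits was taken as within 1.5 times. This tally therefore says little about the counts above 0, whose changes are given with each class. Single tumour genes kept direction and side in 8822 alternative values, lost the threshold in 313, gained it in 112, and changed sign with neither value past it in 119. For single tumour lists these numbers were 1608, 139, 59 and 174, and 7 single J774M lists also changed sign in that way. Genes and lists that passed in neither fit are among those that kept their side. The pilot 1 and unnamed-cluster settings were chosen after seeing the data. With at least 50 cells, T cell models of entinostat and of the 4 arms against vehicle could not be fitted. In T cells (1344), simulated 2-fold changes were recovered at 17.9% with entinostat and 32.1% over the 4 arms, and 4-fold changes at 83.3% and 91.7%. Whether depth, cells or libraries set this was not separated.

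Values that moved or reversed follow, and the cause was not tested except where fewer libraries or genes entered. Camera with an estimated correlation passed 0 lists in J774M and 0 in each tumour contrast. Fry passed 12 in J774M, 2 for entinostat, 4 for the 4 arms and 0 for each antibody arm. In the aggregated libraries alone, share differences were −0.152 (endothelial, 4 arms), −0.015 (endothelial, entinostat), 0.099 (fibroblast, entinostat), −1.51 (neutrophil, 4 arms) and −0.195 (neutrophil, entinostat). Lists numbered 10 (anti-CTLA4) and 13 (anti-PD1). Genes numbered 0 and 1 in T cells (4 arms, entinostat), 0 in epithelial cells (entinostat), 2 in macrophages (4 arms), and 111 and 10 in neutrophils (4 arms, entinostat). DESeq2 gave 0, 1 and 1 genes in T cells (4 arms, entinostat, combined arm) and 86, 22, 5 and 2 in epithelial cells (4 arms, entinostat, anti-CTLA4, combined). It gave 1 and 3 in fibroblasts (anti-CTLA4, entinostat), 81, 56 and 1 in macrophages (4 arms, entinostat, anti-CTLA4) and 1 in neutrophils (anti-PD1). Leiden resolution 0.5 gave 0 in T cells (4 arms), 1 in epithelial cells (entinostat) and 13 and 6 in macrophages (4 arms, entinostat). RLE size factors gave 0 in T cells and 22 in macrophages (4 arms), kept doublets 2 in T cells (4 arms), and unnamed clusters counted as epithelial 1 in epithelial cells (4 arms). With at least 1000 UMIs, share differences were 0.012 (dendritic, entinostat), −0.362 (epithelial, antibody arms), 0.298 (fibroblast, entinostat), −2.35 (neutrophil, 4 arms) and −1.79 (neutrophil, entinostat). As percent of immune cells, macrophage differences were 0.746 (antibody arms), −10.3 (4 arms) and −10.7 (entinostat). With no filter on low counts, genes for 4 arms, entinostat, anti-CTLA4, anti-PD1 and combined arm were 24, 9, 3, 1 and 4 in epithelial cells, 142, 102, 79, 71 and 164 in fibroblasts and 613, 457, 68, 107 and 211 in macrophages. They were 20, 16, 3 and 1 in T cells (all but combined), and 2 and 24 in neutrophils (anti-CTLA4, combined). Without the pilot 1 pair, share differences were 0.361 (fibroblast, entinostat), −1.75 (neutrophil, 4 arms) and −0.873 (neutrophil, entinostat), and genes were 0 in epithelial cells (entinostat) and 116 and 65 in macrophages (4 arms, entinostat).

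With no replicate block in the tumours, that is without the run as a term, differences between runs enter the comparisons that use the antibody arms. These arms have no pilot libraries. In this setting lists numbered 31 (4 arms), 10 (anti-CTLA4) and 15 (anti-PD1). Genes numbered 0 and 0 in T cells (4 arms, entinostat), 19 and 0 in epithelial cells, 0 in macrophages (4 arms) and 3 and 0 in neutrophils. Share differences over the 4 arms were −0.003 (endothelial) and −0.511 (fibroblast), and Tnfaip3 in neutrophils went to −0.00066. Lists pointed the other way, with these adjusted p. In epithelial cells they were glycolysis and proliferation over the 4 arms (0.00636 each), proliferation in the anti-CTLA4 arm (0.582), MHC class I in the anti-PD1 arm (0.00967), and NF-kB (0.951) and proliferation (0.00659) in the combined arm. In fibroblasts it was cholesterol in the anti-PD1 arm (0.869). In macrophages they were NF-kB (0.0327), glycolysis (0.000273) and lysosome (0.0292) over the 4 arms, MHC class II (0.0336) and glycolysis (0.00481) in the anti-CTLA4 arm, NF-kB and glycolysis (0.0252 each) and dissociation (0.561) in the anti-PD1 arm, and MHC class I (0.721), MHC class II (0.648), dissociation (0.767), glycolysis (0.00634) and lysosome (0.0463) in the combined arm.

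Leaving out 1 library in turn gave share differences of −0.318 to 0.239 (dendritic, entinostat), −1.0 to 0.681 (endothelial, antibody arms), −1.42 to 1.85 (epithelial, antibody arms), −0.241 to 1.62, −0.158 to 0.755 and −0.62 to 0.361 (fibroblast, antibody arms, 4 arms and entinostat). They were −3.32 to 1.12 (macrophage, antibody arms), and −1.75 to 5.39 and −0.873 to 6.27 (neutrophil, 4 arms and entinostat). The reversals came without entinostat A (endothelial, epithelial, macrophage) and without combined arm A1, A2 or B1 (epithelial at −0.753, −0.192 and −0.411). Others came without entinostat B (fibroblast, antibody arms, and with vehicle B dendritic and fibroblast at 0.233, entinostat), vehicle A, entinostat p2 or vehicle p2 (fibroblast, 4 arms) and entinostat p1 or vehicle p1 (neutrophil, and fibroblast with entinostat). Gene counts ran from 0 to 8 (4 arms), 0 to 3 (entinostat) and 0 to 2 (anti-PD1) in T cells, 0 to 6 (4 arms), 0 to 7 (entinostat) and 0 to 1 (combined) in epithelial cells. They ran from 0 to 1 (4 arms), 0 to 2 (entinostat) and 0 to 1 (combined) in fibroblasts, 0 to 112 (4 arms), 0 to 74 (entinostat), 0 to 1 (anti-PD1) and 0 to 1 (combined) in macrophages. In neutrophils they ran from 18 to 431 (4 arms), 6 to 228 (entinostat), 0 to 1 (anti-CTLA4) and 0 to 3 (combined).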

Other observations

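The combined arm differed from entinostat alone in several lists not described above. The limit set by the shared entinostat libraries holds here and for the arms below. In epithelial cells, cholesterol biosynthesis had a median log2 fold change of 0.14 (camera adjusted p = 1.33e-05), NF-kB 0.28 and extracellular matrix 0.18 (both adjusted p = 0.00167) and dissociation and heat-shock response 0.17 (adjusted p = 0.00404), each with adjusted p = 0.329 with an estimated correlation. Without the run as a term NF-kB pointed the other way (adjusted p = 0.951). Type I interferon response had a median of 0.12 (adjusted p = 0.0309, and adjusted p = 0.433 with an estimated correlation). In neutrophils, extracellular matrix had a median of 0.86 over 15 genes (1 higher adjusted over the list alone; adjusted p = 0.000189, and adjusted p = 0.626 with an estimated correlation). Its leading member Fn1 (1.21) was at 0.0149 of its fibroblast mean. In macrophages, MHC class I presentation had a median of −0.18 and dissociation and heat-shock response one of 0.21 (both adjusted p = 0.0186, and adjusted p = 0.741 with an estimated correlation). Both pointed the other way without the run as a term (adjusted p = 0.721 and 0.767). In fibroblasts, suppressive myeloid functions had a median of 0.22 (1 higher adjusted over the list alone; adjusted p = 0.0482, and adjusted p = 0.205 with an estimated correlation), where S100a9 was at 0.00183 of its neutrophil mean.

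In fibroblasts, cholesterol biosynthesis was lower in the anti-CTLA4 arm (−0.35, adjusted p = 0.000532, and adjusted p = 0.567 with an estimated correlation) and in the anti-PD1 arm (−0.24, adjusted p = 0.0056, and adjusted p = 0.935 with an estimated correlation). In the anti-PD1 arm it pointed the other way without the run as a term (adjusted p = 0.869). Proliferation genes were lower in the anti-CTLA4 arm (−0.40, adjusted p = 0.000961, and adjusted p = 0.694 with an estimated correlation), and glycolysis and hypoxia was higher (0.21, adjusted p = 0.0196, and adjusted p = 0.765 with an estimated correlation). In epithelial cells of the anti-CTLA4 arm, glycolysis and hypoxia had a median of 0.08 (adjusted p = 0.00272, and adjusted p = 0.93 with an estimated correlation). In macrophages of the anti-PD1 arm, proliferation had a median of 0.24 (adjusted p = 0.00349), cholesterol biosynthesis −0.19 (adjusted p = 0.00385), glycolysis and hypoxia −0.13 (adjusted p = 0.000807; 2 lower adjusted over the list alone) and dissociation and heat-shock response 0.12 (adjusted p = 0.0149), each with adjusted p = 0.806 with an estimated correlation. Without the run as a term glycolysis (adjusted p = 0.0252) and dissociation (adjusted p = 0.561) pointed the other way.

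A hypothesis was that genes changed at least 2-fold in J774M cells move the same way in tumour cells over the 4 entinostat arms, and the 4 tests did not bear it out. Of the 552 genes that rose in J774M, 257 were measured in macrophages and 53.3% were higher there, against 47.8% of all genes (adjusted p = 0.293 with an estimated correlation). In neutrophils 97 were measured and 64.9% were higher, against 50.3% of all genes (adjusted p = 0.293). Of the 128 that fell, 39 were measured in macrophages, 56.4% lower against 52.2% of all genes (adjusted p = 0.665), and 18 in neutrophils, 33.3% lower against 49.7% (adjusted p = 0.281). With the preset correlation the rising genes passed in neutrophils (adjusted p = 0.0354) and the falling genes pointed up there, against the hypothesis (adjusted p = 0.0542), so a shared response stays possible and is not shown.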
